A study of Escherichia coli K-12 with 6 samples.

How the data were processed

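Gene expression was measured by miniBac-seq, a bacterial RNA-seq library method, in 6 libraries of Escherichia coli K-12 strain BW25113. Per the labels' protocols, cells were grown at 37 °C in a microfluidic device in M63B1 medium for about 36 hours, until the biofilm had a radius of 1000 µm, and were then taken out for fluorescence-activated cell sorting. Lysates were made with lysozyme and proteinase K, and RNA was purified on beads, per the labels' protocols. The labels place every library in the biofilm periphery and name 3 groups of 2 replicates: cells called PpyrLBI high, cells called PpyrLBI low, and cells of a ΔsapD strain. The gate that defined high and low, the construct behind the name PpyrLBI and the gate used for ΔsapD are not given in the sources used here. The high and low groups are called reporter groups below, because PpyrLBI is read as the promoter of the pyrLBI operon driving a fluorescent reporter. No wild-type or unsorted library was analysed here.

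The deposited values are raw read counts per gene, with no normalization by the authors that the table shows. Reads were trimmed with cutadapt 2.10 and aligned with Bowtie2 2.4.1, per the submitters' processing notes. The read counter, the genome build, the annotation, the handling of strand and any removal of ribosomal RNA are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies may have traded reads, so such genes are marked as uncertain where they are named. The count table had 4531 gene rows and no column outside the 6 libraries. Against a RefSeq gene table of assembly ASM584v2 (strain MG1655), 4407 rows matched by symbol, 66 by a synonym, and 58 did not match. The unmatched rows held 0.134% to 0.164% of the counts of a library. That table was used only for names and for which genes neighbour each other, and no coordinates are printed because the authors' build is not known.

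Library totals ran from 989561 to 13202303 counts, and 3804 to 4426 genes had at least 1 count. Counts are PCR-amplified reads without molecular identifiers that the sources mention, so floors for zero counts cover counting error only. A gene with 0 counts in both ΔsapD libraries was given a floor of 3 counts over the group, and its fold difference was written as a lower bound. Each library was counted as its own replicate, as the labels number them, and no replicate pair agreed within sampling noise (chi-square per degree of freedom of 12.5 to 146), as 1 library deposited more than once would. That check does not show separate cultures. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

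Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (its default minimum of 10 counts, by group) were kept, which left 3995 genes and removed 536. TMM factors lay between 0.9665 and 1.044. All 6 libraries entered 1 quasi-likelihood fit (glmQLFit, robust) with group as the only term, leaving 3 residual degrees of freedom, because 2 libraries per group give a poor estimate of spread alone. The common dispersion was 0.13. The first contrast was PpyrLBI high minus PpyrLBI low, and the second was ΔsapD minus the mean of the reporter groups on the log2 scale. P-values from glmQLFTest were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, as the size of the fold change over the square root of F. Means ± SD are of TMM-adjusted CPM (counts normalised to library size), except the floors and the folds built on them, which use library totals. Adjusted p-values of single genes in the text are from this edgeR test unless another tool is named.

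Before the data were examined, 38 gene lists were fixed, covering metabolism, stress responses, surface structures and respiration. They included acid resistance, RpoS-dependent and anaerobic genes as markers of cells from deeper in the biofilm, which a periphery sample could also hold. The last list, genes deleted in the parent strain, was a check and was not tested. For the other 37, camera of limma 3.58.1 was run on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. Each call is given also with the correlation estimated per list, and fry was run as an alternative that asks whether a list's genes move one way on balance. Members were counted after adjustment over all genes and after adjustment over the list alone. Genes were named by a rule fixed before the data were examined. Among genes past the threshold whose libraries did not overlap between the sides and whose mean CPM was at least 20, the rule took the 10 largest log2 fold changes per direction. With fewer than 5 such genes in a direction, it took the 5 smallest unadjusted p-values among genes meeting the other criteria and gave them as values. It also took pyrL, pyrB, pyrI, carA, carB and the 5 sap genes in every case, and up to 4 members with the smallest p of each called list. Genes named outside the rule are said to be chosen after their values were seen.

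The same code was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For the high against low comparison, run on 3936 simulated genes, edgeR recovered 6% of the 2-fold and 48% of the 4-fold changes, and 7 of its 61 calls were false. For the ΔsapD comparison, run on 3937 genes, it recovered 6% and 53%, and 5 of its 64 calls were false. A simulated list shifted 2-fold was called by camera with the preset correlation (adjusted p = 3.22e-12 for high against low and 1.62e-12 for ΔsapD). With an estimated correlation the same list was missed in both comparisons (adjusted p = 0.418 and 0.297), and fry also missed it (adjusted p = 0.302 and 0.082). Simulated genes varied independently, whereas the estimated correlation of real lists reached 0.93 (autoinducer-2 uptake). The simulation therefore cannot show whether preset calls hold for lists of correlated genes. The test with an estimated correlation missed a shifted list of independent genes. A call lost in it is therefore not shown to rest on correlated genes.

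Alternatives fixed before the data were examined were DESeq2 size factors, no factors, no filter, a stricter filter (10 counts in each library of a group and a mean of 20), DESeq2 1.42.0, limma voom, removal of rRNA and tRNA rows, and the replicate number as a block. Further ones were a 2-fold minimum, a fit of the 4 reporter libraries alone with and without the block, each reporter group alone as comparator for ΔsapD, and each library left out in turn. A block for the reporter libraries only and counts thinned to the smallest library's total were added after the data were seen.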

Results

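Transcript counts were obtained from cells of the periphery of E. coli biofilms grown for about 36 hours in a microfluidic device. The 6 libraries fell into 3 groups of 2: cells sorted as PpyrLBI high, cells sorted as PpyrLBI low, and cells of a strain without sapD. PpyrLBI is read here as the promoter of the pyrLBI operon, which encodes the leader peptide PyrL and both subunits of aspartate transcarbamoylase, the enzyme that commits carbamoyl phosphate to pyrimidine synthesis. The sap genes are annotated as encoding an ABC transporter. Library totals (replicates 1 and 2) were 13202303 and 4866380 counts for the high group, 4114629 and 7960692 for the low group, and 2781637 and 989561 for ΔsapD. The ΔsapD libraries were therefore the shallowest on average, and low counts there limit the precision of that comparison, along with the spread between libraries. Ribosomal RNA genes held 0.154% and 0.34% of counts in ΔsapD and 0.0101% to 0.0985% in the reporter groups.

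The deleted gene was examined first. No sapD read was counted in ΔsapD among 3771198 counts, whereas each reporter library held 278 to 938 sapD counts (76.1 ± 9.13 CPM of library totals, SD, n = 4). With a floor of 3 counts over the group, 0.796 CPM, sapD was at least 95.7-fold lower in ΔsapD (at least 25.1-fold without ΔsapD replicate 1, which held most of that group's counts). The other sap genes did not pass the edgeR test in ΔsapD: log2 fold changes against the reporter groups were 0.16 ± 0.21 (SE) for sapA, -0.61 ± 0.31 for sapB, -0.64 ± 0.44 for sapC (-1.14 without ΔsapD replicate 1 and -0.278 without replicate 2) and 0.85 ± 0.32 for sapF. The sapD and sapC genes overlap in the RefSeq annotation, so their counts may not be fully separate. The 7 genes deleted in the BW25113 parent (araBAD, rhaBAD and lacZ) together held 20 of 33915202 counts.

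The first comparison asked, as the group names are read here, which transcripts differ between peripheral cells with high and with low activity of the pyrLBI promoter. Several genes of de novo pyrimidine synthesis lay higher in high cells. The carbamoyl phosphate synthetase genes carA and carB had log2 fold changes of 1.35 ± 0.24 (SE) and 1.27 ± 0.22, with carB at 1660 ± 206 CPM in high and 687 ± 119 CPM in low cells (SD, n = 2 each). The aspartate transcarbamoylase genes pyrB and pyrI had 1.01 ± 0.21 and 1.11 ± 0.24, with pyrB at 577 ± 36.8 against 287 ± 19.0 CPM. Both lie in the operon whose promoter names the sort, so a difference in them may follow from the gate itself. For the leader gene pyrL itself, the log2 fold change was 0.09 ± 0.40, from 33.9 ± 10.1 CPM in high and 31.8 ± 1.22 CPM in low cells, a difference smaller than its error (-0.257 without high replicate 2 and 0.366 without high replicate 1). Of the 12 pyrimidine biosynthesis genes, 11 had positive fold changes (median 0.76), and carA, carB, pyrB and pyrI passed when adjusted over the list alone, while 0 of 12 passed over all genes tested. Beyond these and pyrL, pyrH (0.65 ± 0.24), ndk (0.86 ± 0.50) and pyrE (0.87 ± 0.67) were positive. The values of pyrD (0.23 ± 0.32), pyrF (0.13 ± 0.33), pyrC (0.08 ± 0.33) and pyrG (-0.19 ± 0.26) were within their SE. With pyrB and pyrI counted in it, the list was called by camera (adjusted p = 6.11e-05, preset correlation). The call was lost with an estimated correlation (adjusted p = 0.32). The lists set in advance as markers of deeper biofilm cells lay lower in high cells. Their medians were -1.5 for acid resistance, -0.61 for RpoS and -1.1 for anaerobic genes. Position within the biofilm was not measured, so this does not show a difference in depth.

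With group as the only term, edgeR called no single gene across all genes in this comparison. In that fit, 0 of 3995 genes had an adjusted p under 0.05 (the smallest was 0.47), although 282 had an unadjusted p under 0.05 (175 higher and 107 lower in high cells), where chance gives 200. DESeq2 called 33 genes (19 higher, 14 lower) and limma voom called 0, with 296 and 346 at an unadjusted p under 0.05. Whether libraries of the same replicate number shared a biofilm is not given in the sources used here, and the count of genes depends on that. With the replicate number as a block, the count was 0 over all 6 libraries. It was 426 in a fit of the 4 reporter libraries alone, which leaves 1 residual degree of freedom. The block over all 6 libraries also ties in the ΔsapD libraries, which did not deviate with the high or low libraries (correlation -0.19 and -0.23). Its count of 0 therefore does not settle whether the reporter libraries are pairs. A block for the reporter libraries only, added after the data were seen, gave 26. The genes with the smallest p on the high side, given as values only, were codB (cytosine permease, log2 fold change 1.60 ± 0.26, 279 ± 75.7 against 91.8 ± 13.2 CPM), carB, rpmF (ribosomal protein L32, 1.68 ± 0.29), carA and ghxP (a guanine and hypoxanthine transporter, 1.28 ± 0.24). On the low side they were appC (a cytochrome bd-II oxidase subunit, -2.15 ± 0.41, 35.3 ± 3.90 against 156 ± 67.1 CPM), hdeB (an acid stress chaperone, -1.59 ± 0.32), leuA (leucine synthesis, -0.98 ± 0.21), mdtE (a multidrug efflux protein, -2.13 ± 0.45) and hdeA (-1.59 ± 0.35). All 10 had an edgeR adjusted p of 0.47. Their high and low libraries did not overlap, but that held for 36.3% of all genes tested, where chance gives 33.3%. The sap genes had log2 fold changes between -0.34 (sapF) and 0.01 (sapD), each within its SE, and the signs of sapB, sapC, sapD and sapF changed under some settings. On simulated data this design recovered 6% of 2-fold and 48% of 4-fold changes.

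**Figure D1:**
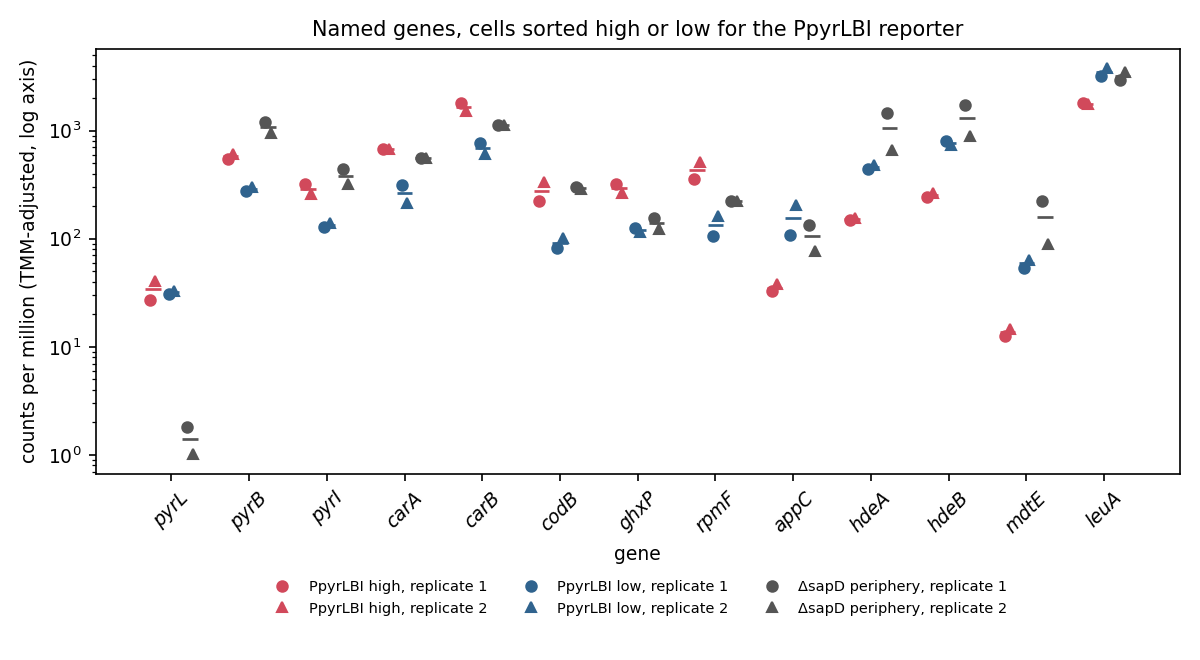
TMM-adjusted CPM (log axis) of 13 named genes in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each pair. For carB the high libraries average 1660 and the low libraries 687, for hdeB 256 and 769, while for pyrL the high and low libraries overlap and the ΔsapD libraries average 1.41.

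Ribosomal protein and aerobic respiration genes lay higher in high cells as groups, where the acid resistance, RpoS and anaerobic markers lay lower. Of 54 ribosomal protein genes, 52 had positive log2 fold changes (median 0.66), 32 passed when adjusted over the list alone, and 0 passed over all genes tested. Examples were rpmF (1.68 ± 0.29), rplR (1.20 ± 0.28), rplQ (1.31 ± 0.31) and rplW (0.75 ± 0.19), with rplR at 0.76 without high replicate 2 and rplQ at 0.789 without high replicate 1. Of 22 genes of the aerobic respiratory chain (NADH dehydrogenase I, cytochrome bo oxidase and succinate dehydrogenase), 21 were positive (median 0.73) and 12 passed when adjusted over the list alone, among them nuoL (0.94 ± 0.20), nuoN (1.19 ± 0.28) and cyoC (1.08 ± 0.27). Camera called both lists (adjusted p = 9.84e-23 and 1.52e-11). With an estimated correlation neither call held (adjusted p = 0.15 for each), whereas fry, which tests a common direction, gave adjusted p = 0.033 for ribosomal proteins and 0.008 for the respiratory chain. The estimated correlation was 0.057 for ribosomal proteins and -0.045 for the respiratory chain. The latter is below the preset 0.01, so correlated genes do not account for the loss of the respiratory chain call.

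Acid resistance, stress and anaerobic genes lay lower in high cells. Of 12 acid resistance genes, 11 had negative log2 fold changes (median -1.5) and 9 passed when adjusted over the list alone, including the periplasmic chaperone genes hdeA (153 ± 4.03 against 462 ± 24.4 CPM) and hdeB (256 ± 15.8 against 769 ± 54.0 CPM) and the regulator gadE (-1.49 ± 0.40). Of 30 genes of the list for RpoS general stress and stationary phase, 27 were negative (median -0.61) and 0 passed even when adjusted over the list alone. The trehalose synthesis genes otsA and otsB had -0.91 ± 0.21 and -1.02 ± 0.25. Among 46 genes of the list for anaerobic respiration and fermentation, 41 were negative (median -1.1). The oxidase subunit gene appC alone passed when adjusted over the list alone, and an oxidase is not in itself an anaerobic enzyme. Of the other cytochrome bd oxidase genes in the list, appB was negative (-2.06 ± 0.47), while cydA (0.50 ± 0.29) and cydB (0.15 ± 0.38) were positive. The anaerobic ribonucleotide reductase gene nrdD had -1.32 ± 0.32 and the alcohol dehydrogenase gene adhE -1.24 ± 0.37, which became -0.79 and -0.745 without low replicate 2. All 15 formate hydrogenlyase genes were negative (median -2.1) with 0 passing when adjusted over the list alone, and hycG (-2.70 ± 0.70) counted only 6.71 ± 3.15 CPM in high cells. Camera called the lists with adjusted p = 2.1e-08, 3.23e-07, 8.13e-07 and 1.69e-05 in this order, and with an estimated correlation all 4 calls were lost (adjusted p = 0.51, 0.51, 0.67 and 0.67). The anaerobic call was also lost without high replicate 1 or low replicate 2, and the formate hydrogenlyase call without low replicate 2.

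A further 10 lists were called in high against low cells, in each of which 0 members passed over all genes or when adjusted over the list alone. Purine biosynthesis (12 of 15 positive, median 0.40, purL 0.65 ± 0.20), arginine biosynthesis (9 of 9, median 0.39, argG 0.71 ± 0.19), ATP synthase (8 of 9, median 0.35, atpE 0.55 ± 0.19), methionine and cysteine biosynthesis (16 of 24, median 0.23, cysM 0.81 ± 0.20) and iron uptake (27 of 40, median 0.14) lay higher. In the iron list the siderophore receptor genes fiu (1.34 ± 0.41) and cirA (1.05 ± 0.37) had the smallest p. Toxin-antitoxin systems (17 of 20 negative, median -0.44, mazE -0.58 ± 0.28), catabolite-repressed sugar uptake (49 of 58, median -0.34, gatZ -0.55 ± 0.19), autoinducer-2 uptake (9 of 9, median -1.4, lsrK -1.27 ± 0.81), glycolysis (14 of 17, median -0.30, fbaA -0.51 ± 0.21) and curli fibres (5 of 6, median -0.83, csgD -0.69 ± 0.37) lay lower. Camera adjusted p ranged from 0.000233 for purines to 0.0383 for iron uptake, and with an estimated correlation none of the 10 held (adjusted p from 0.32 to 0.67). Without high replicate 1 the calls of toxin-antitoxin systems, arginine, curli and iron were lost. Without low replicate 1 the calls of ATP synthase, autoinducer-2, sugar uptake and curli were lost, without high replicate 2 those of autoinducer-2, sugar uptake, glycolysis, curli and methionine and cysteine, and without low replicate 2 those of purines, glycolysis, iron, curli and methionine and cysteine. Single values also rested on 1 library: without low replicate 1 lsrK was -0.00183 and csgD -0.363, without high replicate 1 lsrK was -2.32, and cirA was 1.71 without low replicate 1 and 0.601 without low replicate 2. The remaining 20 lists were not called, among them pyrimidine uptake and salvage (adjusted p = 0.29), whose median of -0.024 and mean of 0.22 differ in sign. In that list codB, the uracil permease gene uraA (1.55 ± 0.29) and the cytosine deaminase gene codA (1.05 ± 0.28), the last 2 chosen after their values were seen, passed when adjusted over the list alone.

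**Figure D2:**
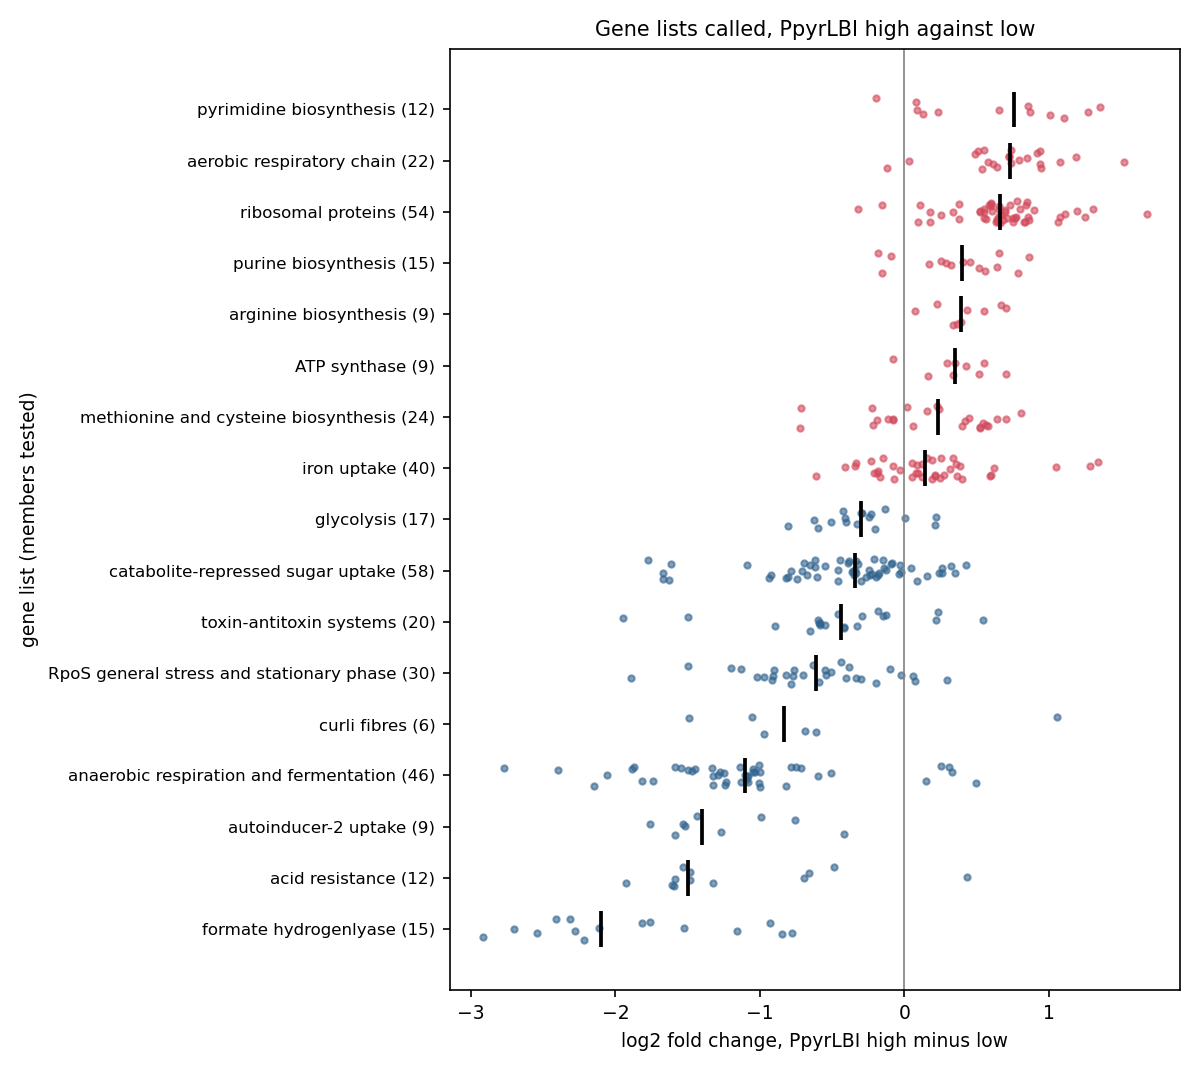
Log2 fold changes, PpyrLBI high minus low, of the members of the 17 gene lists called with the preset correlation (points; red for lists higher and blue for lists lower in high cells), with a black bar at each list's median. Medians run from -2.1 for formate hydrogenlyase to 0.76 for pyrimidine biosynthesis.

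The second comparison set ΔsapD cells against the mean of both reporter groups. The groups differ in genotype, and whether they also differ in reporter and sort gate is not given in the sources used here, so a difference cannot be assigned to the deletion. By edgeR, 458 of 3995 genes passed an adjusted p of 0.05, 230 higher and 228 lower in ΔsapD, and 368 of them differed at least 2-fold. Over all genes tested, both ΔsapD libraries lay above or both below all 4 reporter libraries in 1659 (41.5%), an arrangement that chance gives in 13.3%. The count rested on the replicates of each side: without ΔsapD replicate 1 it was 0, without ΔsapD replicate 2 it was 13, without high replicate 1 it was 231, and without high replicate 2 it was 118. Every single-gene call given for ΔsapD was thus lost when ΔsapD replicate 1 was left out, which leaves 1 library in that group. Among the 3 lists set in advance as markers of deeper biofilm cells, acid resistance (median 1.2) and RpoS genes (median 0.53) lay higher in ΔsapD. Both camera calls were lost with an estimated correlation (adjusted p = 0.74 and 0.79). The third, anaerobic genes, was not called (median -0.14, 28 of 46 negative, 0 passing, adjusted p = 0.612). Against the high group alone 297 genes passed and against the low group alone 140, while DESeq2 called 773 and limma voom 156.

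Genes of type 1 fimbriae, the adhesive surface fibres, were far lower in ΔsapD. Of 9 list members 8 fell, both over all genes and when adjusted over the list alone (median log2 fold change -3.5). The chaperone gene fimC fell from 764 ± 84.8 CPM in reporter cells (SD, n = 4) to 47.5 ± 11.5 CPM in ΔsapD (n = 2), a log2 fold change of -3.99 ± 0.26 (adjusted p = 0.00249). The minor subunit genes fimF (-4.27 ± 0.35) and fimG (-3.20 ± 0.35) and the adhesin gene fimH (-3.39 ± 0.36) also fell. The recombinase gene fimB, at -0.09 ± 0.60, was the member that did not pass. The major subunit gene fimA held the largest share of counts in each reporter library (2.86% to 4.45%) and 0.472% and 0.204% in ΔsapD, where the elongation factor gene fusA ranked first. Camera called the list (adjusted p = 2.99e-06). With an estimated correlation the call was lost (adjusted p = 0.73), and fry gave adjusted p = 0.022. Without ΔsapD replicate 1 the adjusted p of fimC was 0.0582.

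Of the 10 largest decreases in ΔsapD named by the rule, 5 were of cold-shock protein genes, which encode small RNA-binding proteins. The cspA transcript averaged 5595 ± 2410 CPM in reporter cells and 27.3 CPM in ΔsapD (34.3 and 20.2 in its libraries, log2 fold change -7.61 ± 0.66, adjusted p = 0.00786). The related genes cspB (-8.85 ± 0.57), cspG (-8.13 ± 0.79) and cspI (-8.83 ± 1.09) also fell, the last on 4 counts, all in ΔsapD replicate 1. Among genes with 0 ΔsapD counts, cspF was at least 48.8-fold lower, ymcF, which neighbours cspG, at least 59.4-fold, and ynfQ, which neighbours cspI, at least 99.7-fold (12.8, 15.6 and 26.2 without ΔsapD replicate 1). The prophage genes ydfK (-7.59 ± 0.82, 6 counts) and ynaE (-7.58 ± 1.02, 7 counts, all in ΔsapD replicate 1) also passed, but they are near-identical copies between which reads cannot be placed with certainty. Members of the csp family are similar in sequence, and ymcF overlaps ymcE in the RefSeq annotation, so their single values are uncertain too. Without ΔsapD replicate 1 none of these genes passed, with edgeR adjusted p of 0.0582 for cspB and 0.123 for cspA, and against the low group alone cspF, ymcF and ynfQ did not pass. With limma voom cspF, ymcF, ynfQ, cspI, ydfK and ynaE did not pass (adjusted p from 0.0928 to 0.139), nor did cspF without high replicate 2 (0.0541) or ynfQ without low replicate 2 (0.0601).

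Among the 10 largest increases, stpA, which encodes a nucleoid protein related to H-NS, rose from 6.39 ± 2.58 to 109.5 ± 59.3 CPM (log2 fold change 4.15 ± 0.42, adjusted p = 0.00764). In the acid resistance region, slp (2.47 ± 0.24) and dctR (2.53 ± 0.33) are neighbours, as are the small RNA gene gadF (2.77 ± 0.41) and the efflux gene mdtE (2.49 ± 0.36). The rest were rdgC, a recombination-associated gene (2.51 ± 0.25), argI, an ornithine carbamoyltransferase gene (2.44 ± 0.22), upp, the uracil phosphoribosyltransferase gene (2.34 ± 0.30), yhaH (2.17 ± 0.40) and yciF (2.16 ± 0.31). As a list, acid resistance lay higher in ΔsapD, with positive values in 12 of 12 members (median 1.2). The genes hdeA (2.00 ± 0.29), hdeB (1.56 ± 0.26) and gadE (1.81 ± 0.32) rose, and 7 of 12 rose when adjusted over the list alone. In the list for RpoS general stress and stationary phase, 5 of 30 genes rose over all genes and 9 when adjusted over the list alone (median 0.53). The 5 were slp, wrbA (1.42 ± 0.23), uspA (1.29 ± 0.23), dps (1.91 ± 0.38) and, chosen after its value was seen, cbpA (1.05 ± 0.25). Camera adjusted p was 0.000168 for acid resistance and 0.00179 for RpoS, and neither held with an estimated correlation (adjusted p = 0.74 and 0.79). Against the low group alone gadF, mdtE, yhaH, hdeA, hdeB, gadE, wrbA and dps no longer passed (log2 fold change 0.77 for hdeB, 1.06 for gadE, 1.20 for hdeA and 1.42 for mdtE), and against the high group alone uspA did not. Without ΔsapD replicate 1 the adjusted p of stpA was 0.123 and mdtE, hdeA and hdeB were at 1.65, 1.33 and 1.00, and without high replicate 2 it was 0.0581 for hdeB and 0.0788 for dps.

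**Figure D3:**
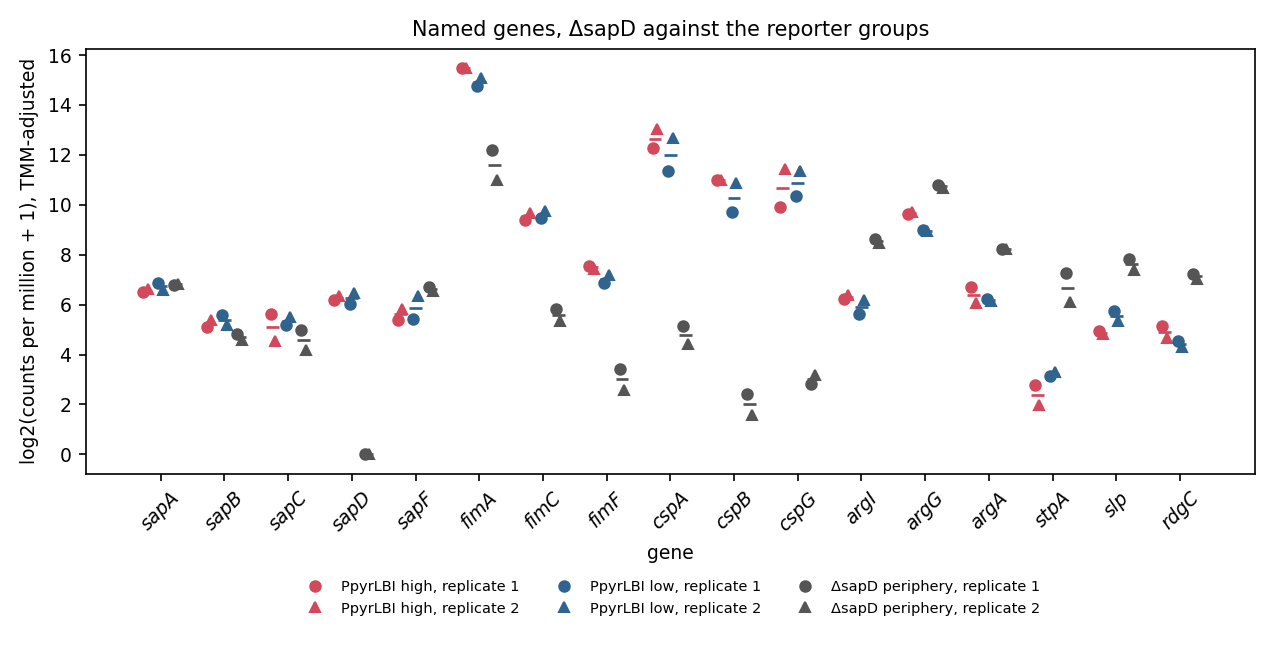
Expression of 17 named genes as log2(TMM-adjusted CPM + 1) in each of the 6 libraries, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each pair on that scale. No sapD counts were seen in ΔsapD, and cspA falls from a mean of 5595 to 27.3 CPM while argI rises from 69.4 to 375.

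Arginine synthesis and glycolysis genes were higher in ΔsapD. Of 9 arginine biosynthesis genes, argI (375 ± 24.6 against 69.4 ± 15.2 CPM, adjusted p = 0.00651), argG (1.43 ± 0.16), argA (1.93 ± 0.23), argF (1.60 ± 0.21) and, chosen after its value was seen, argB (0.78 ± 0.18) rose over all genes, and 8 rose when adjusted over the list alone (median 0.89). Of 17 glycolysis genes, 11 rose over all genes and 13 when adjusted over the list alone (median 0.77), with tpiA at 1.58 ± 0.19, gapA at 1.51 ± 0.26, pgi at 1.26 ± 0.21 and pykF at 1.04 ± 0.16. Camera called both (adjusted p = 4.46e-05 for arginine and 5.21e-06 for glycolysis). With an estimated correlation both calls were lost (adjusted p = 0.63 and 0.64), while fry gave adjusted p = 0.0057 and 0.019. The estimated correlation was -0.045 for arginine and 0.079 for glycolysis. The former is below the preset 0.01, so correlated genes do not account for the loss of the arginine call. Against the low group alone pgi and gapA did not pass, and without ΔsapD replicate 1 the adjusted p of argI and of tpiA was 0.123.

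Some nucleotide synthesis genes rose in ΔsapD, whereas the pyrL leader gene and the purine gene prs fell. The pyrB transcript rose from 432 ± 169 to 1076 ± 172 CPM (log2 fold change 1.40 ± 0.17, adjusted p = 0.00852) and pyrI rose by 0.95 ± 0.20 (adjusted p = 0.0342), as did the dihydroorotase gene pyrC (1.23 ± 0.28). The leader gene pyrL fell from 32.9 ± 5.97 to 1.41 ± 0.56 CPM, on 6 counts in ΔsapD (-4.39 ± 0.52, adjusted p = 0.0085). The genes carA (0.40 ± 0.20) and carB (0.08 ± 0.19) did not pass, and against the high group alone both changed sign. Of the 12 pyrimidine genes, 11 had positive log2 fold changes, and 3 rose and 1 fell over all genes (5 rose and 1 fell when adjusted over the list alone, median 0.73). Of 15 purine genes, 12 were positive, and purH (1.28 ± 0.20), purM (0.87 ± 0.17) and purT (1.00 ± 0.23) rose and prs, chosen after its value was seen, fell (-0.90 ± 0.21) over all genes, with 4 rising and 1 falling when adjusted over the list alone (median 0.50). Camera adjusted p was 0.0122 for pyrimidines and 0.0147 for purines, both lost with an estimated correlation (adjusted p = 0.73 and 0.79) and without ΔsapD replicate 1. The purine call was also lost with the replicate block for the reporter libraries only. Against the high group alone pyrB had 0.90, pyrI (log2 fold change 0.39) and purM (0.55) no longer passed, and pyrC and purT did not pass against either group alone. With limma voom pyrL (adjusted p = 0.051), pyrI, pyrC and purT did not pass, nor did pyrI, pyrC, purM and purT without high replicate 1 (0.0575 to 0.0737), these and purH without high replicate 2 (0.0524 to 0.114), or purT without low replicate 2 (0.0565) or in thinned counts (0.0521).

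SOS response genes, which are induced by DNA damage, were lower in ΔsapD, with 8 of 24 falling and 1 rising over all genes and 14 falling and 1 rising when adjusted over the list alone (median -1.1). Among those that fell were yebG (-2.79 ± 0.38), the repressor gene lexA (-1.81 ± 0.28), dinG (-2.10 ± 0.38) and the excision repair gene uvrA (-1.21 ± 0.19), and dinI, chosen after its value was seen, rose (1.54 ± 0.34). Of 58 catabolite-repressed sugar uptake genes, 11 fell and 1 rose over all genes, and 12 fell and 1 rose when adjusted over the list alone (median -0.69). The maltose transporter genes malK (-2.84 ± 0.46) and malF (-1.76 ± 0.33) and the galactitol genes gatZ (-1.09 ± 0.18) and gatD (-1.12 ± 0.19) were among them, and galM, chosen after its value was seen, rose (0.66 ± 0.17). Camera adjusted p was 0.000258 for SOS and 0.00179 for sugar uptake, and neither held with an estimated correlation (adjusted p = 0.74 and 0.79). Leaving out ΔsapD replicate 1 also ended the sugar uptake call, and against the high group alone gatZ and malF did not pass. With limma voom yebG, dinG, malK and malF did not pass (adjusted p from 0.0588 to 0.0939), nor did uvrA, dinG and malF without high replicate 2 (0.0509 to 0.0584) or malF without high replicate 1 (0.0546).

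The other 3 of the 12 lists called in ΔsapD concerned sulfur amino acids, ATP synthase and surface polysaccharides. Methionine and cysteine biosynthesis lay higher (median 0.49, adjusted p = 0.00799), with metQ (0.83 ± 0.16), cysA (0.76 ± 0.18), cysP (0.77 ± 0.18) and cysK (0.75 ± 0.19) rising over all genes (metQ not against the low group alone, and the cys genes against neither reporter group alone) and 7 of 24 rising and 1 falling when adjusted over the list alone. ATP synthase lay higher (median 0.41, adjusted p = 0.0177), with atpE (0.73 ± 0.16) the 1 of 9 genes that rose on either count, though not against the high group alone (0.45). Cellulose and colanic acid genes lay lower (median -1.9, or -1.7 with the 4 members without ΔsapD counts set at their bound, adjusted p = 0.0164), although 0 of 24 passed on either count. There wza and wcaC had 0 counts in ΔsapD. In the high and low libraries wza had 14.9 and 22.4 CPM in replicate 1 but 1.28 and 2.60 in replicate 2, and wcaC had 8.66 and 9.78 but 0.638 and 2.48, the lowest under the floor of 0.796 CPM. The gene bcsA had -1.75 ± 0.51, and cpsG, with 4 counts in ΔsapD, had -3.41 ± 1.37 (-2.20 without low replicate 1). With an estimated correlation these calls were lost (adjusted p = 0.73, 0.79 and 0.80), as they were without ΔsapD replicate 1. Without ΔsapD replicate 2 the ATP synthase call was lost too, without high replicate 1 those of ATP synthase and cellulose and colanic acid, and without low replicate 1 the latter. Of the single genes, metQ, cysA, cysP, cysK and atpE did not pass without high replicate 1 (adjusted p from 0.0549 to 0.118) or high replicate 2 (0.0581 to 0.0994), the cys genes without low replicate 1 (0.0522 to 0.0575), cysP and cysK without low replicate 2 (0.0625 and 0.0609), and the cys genes and atpE with limma voom (0.0588 to 0.0664). With the replicate block over all 6 libraries, cysP (edgeR adjusted p = 0.055) and cysK (0.0574) did not pass either. Camera did not call the other 25 lists, of which fry called aromatic amino acid biosynthesis (adjusted p = 0.017) and the sap operon (adjusted p = 0.0041), the latter a check of the deletion. Among the others were ribosomal proteins (adjusted p = 0.986).

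**Figure D4:**
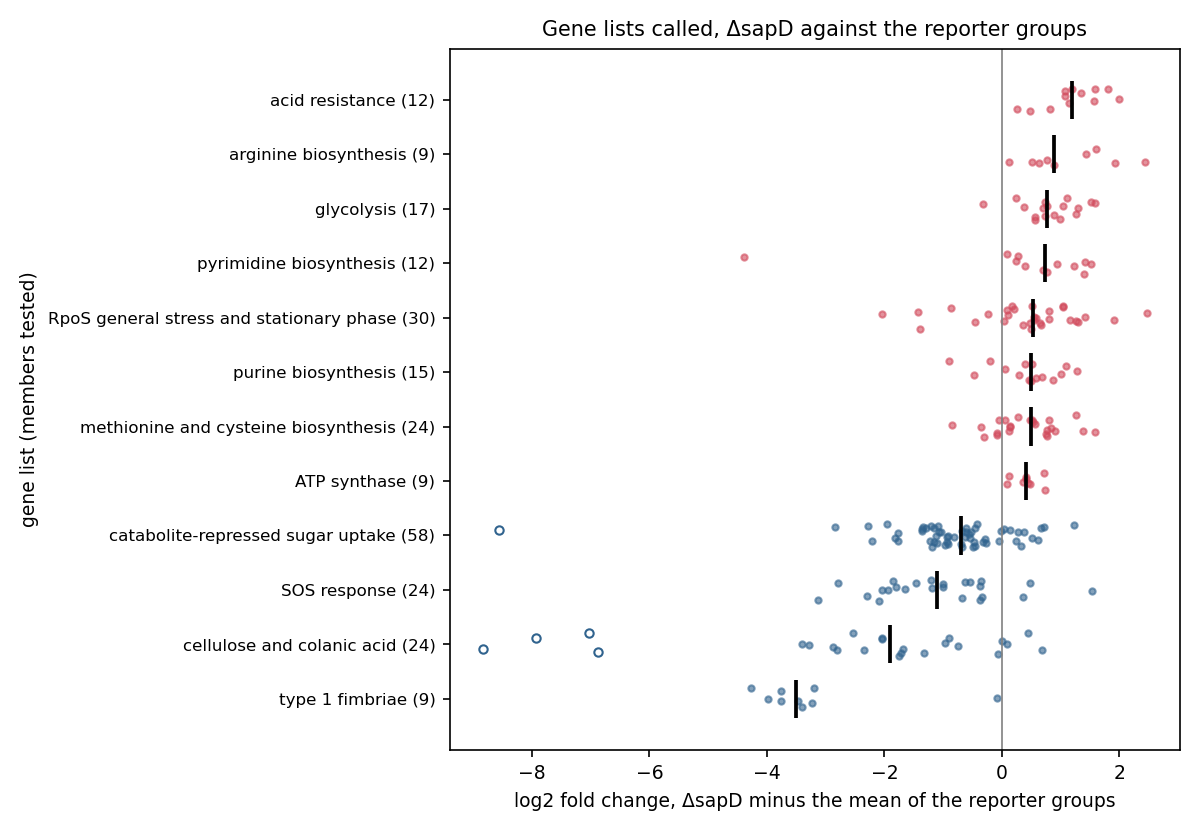
Log2 fold changes, ΔsapD minus the mean of the reporter groups, of the members of the 12 gene lists called with the preset correlation (red for lists higher and blue for lists lower in ΔsapD), with a black bar at each list's median. Open points are genes with 0 counts in both ΔsapD libraries, whose fitted value depends on the prior count and is no measurement; medians run from -3.5 for type 1 fimbriae to 1.2 for acid resistance.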

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

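The reporter-only block and the thinning were chosen after the data were seen. For high against low, the 0 genes of the edgeR fit became 33 with DESeq2, 26 with a replicate block for the reporter libraries only, and 426 (166 higher, 260 lower) with the replicate block in a fit of the 4 reporter libraries alone, which leaves 1 residual degree of freedom. The count was 0 under all other settings, including a replicate block over all 6 libraries and each library left out (0 to 0). Same-numbered high and low libraries deviated together (correlation 0.57). Their log2 CPM across genes correlated at 0.964 and 0.966, against 0.956 within the high, 0.94 within the low and 0.923 within the ΔsapD group. The ΔsapD libraries did not deviate with them (-0.19 and -0.23). Those are of another strain, so this does not bear on the reporter pairs. With 2 pairs and no label that ties the numbers to a shared biofilm, the libraries were not taken as pairs in the main fit. If each number does mark 1 biofilm, a fit blocked over the reporter libraries would be the fitting one, not a block shared with ΔsapD. The 17 lists became 0 with an estimated correlation, 2 with fry, 16 with the replicate block (iron uptake was lost), 17 with the reporter-only block (of which 16 were among the first 17, curli being lost), and 13 to 18 with a library left out.

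For ΔsapD, the 458 genes became 773 with DESeq2, which contained all 458. They became 156 with limma voom (104 higher, or 66.7% against 50.2% in the edgeR fit), 297 against high alone, and 140 against low alone. The range was 0 to 449 with a library left out. Removing a ΔsapD library leaves 1, which is assumed to vary like the other groups. With the replicate block the count was 373, and with the reporter-only block it was 687. Thinned to 989561 counts per library it was 382, of which 352 were among the 458. Unequal depth alone therefore did not produce those 352 calls. The 12 lists became 0 with an estimated correlation, 5 with fry, 13 with the replicate block, and 7 to 14 with a library left out. With the reporter-only block there were 15 lists, of which 11 were among the 12, purine biosynthesis being lost. The cause of these shifts was not tested, apart from unequal depth by thinning. Leaving out a library removes its values and lowers the number of libraries together.

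Of 1392 values of named genes for high against low, 1295 kept direction and side of the threshold, 80 newly passed and 17 changed sign. Of 1313 for ΔsapD, 1105 kept both, 187 no longer passed, 17 newly passed and 4 changed sign. Every sign change concerned a gene that had not passed, and the cause was not tested. For high minus low, pyrL was -0.0277 with limma voom. For sapD it was -0.0694 without factors, -0.00212 without a filter, -0.00484 with the stricter filter, -0.0205 with limma voom, -0.0569 when thinned and -0.000307 with the 4 reporter libraries alone, and sapC was 0.143 when thinned. With a library left out, values ranged from -0.257 to 0.366 for pyrL, -0.343 to 0.0747 for sapB, -0.849 to 0.288 for sapC, -0.188 to 0.239 for sapD, -0.732 to 0.215 for sapF, -2.33 to 0.321 for lsrG and -2.85 to 0.0727 for lsrD. For ΔsapD minus reporter, carA was -0.276 and carB -0.555 against high alone, and carB was -0.0623 with the reporter-only replicate block, and with a library left out carB ranged from -0.00162 to 0.176.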

Other observations

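Of the 25 lists that camera did not call in ΔsapD, 16 had at least 1 member passing the edgeR test, and 4 of these, chosen after their values were seen, are described here. In the list of arginine and putrescine uptake, breakdown and export, which camera did not call (adjusted p = 0.664), the arginine-binding protein genes artJ (log2 fold change 1.46 ± 0.26, adjusted p = 0.0205) and artI (0.94 ± 0.22) rose, as did the arginine transporter ATPase gene artP (1.42 ± 0.26) and the spermidine-binding protein gene potD (1.49 ± 0.26). The putrescine degradation gene puuA fell (-1.44 ± 0.22), and the other 30 of 35 members did not pass. Among the 16 pyrimidine uptake and salvage genes (list adjusted p = 0.109), upp, udk (1.02 ± 0.21), codB (0.89 ± 0.22) and deoD (0.79 ± 0.20) rose and 0 fell. Of 19 heat shock genes (list adjusted p = 0.212), groS (1.49 ± 0.19), groL (0.78 ± 0.19), grpE (0.90 ± 0.21) and htpG (0.70 ± 0.16) rose and 0 fell. Of 40 iron uptake genes (list adjusted p = 0.313), 7 fell and tonB rose (1.02 ± 0.23). The genes named were also chosen after their values were seen. Without ΔsapD replicate 1, 0 genes passed in the comparison, and without ΔsapD replicate 2, 13 did.

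In high against low cells, hexuronate uptake and breakdown genes, a group picked after the data were seen, had negative log2 fold changes in 8 of 9 members (median -1.4). The values were -1.80 ± 0.41 for uxaA, -1.66 ± 0.42 for uxaC and -1.37 ± 0.39 for uxuA, which fell when adjusted over the list alone, and eda rose on that count (0.84 ± 0.29), while 0 of 9 passed over all genes. Camera gave an unadjusted p of 0.000154 with the preset and 0.15 with an estimated correlation. The tRNA genes were also a group outside the lists fixed in advance, so the camera p-values of both groups are descriptive only. Of 51 tRNA genes, 39 had positive values in high cells (median 0.42, camera unadjusted p = 3.8e-06, 0.29 with an estimated correlation), and 0 passed when adjusted over the list alone. In ΔsapD the tRNA median was 0.009 (unadjusted p = 0.344). Many tRNA genes are near-identical copies, so single values are uncertain.

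Of the tests below, those on the summed csp family, on fimA and on the ratio of pyrL to pyrB were chosen only after the results were seen, and those on the other cold-induced genes and on fimB and fimE were written before.

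Reads traded within the csp family do not account for its decrease in ΔsapD, because summed CPM of cspA to cspI were 114 and 146 in the ΔsapD libraries and 5340 to 14180 in the reporter libraries, with a smallest log2 difference between any 2 such libraries of -5.19. A candidate explanation is that reporter cells met cold after growth, for example during sorting, and ΔsapD cells did not. The other cold-induced genes had a median log2 fold change of -0.762 over 12 genes, between the bounds set in advance (-1 and -0.5). Of the 12, 10 were negative, lpxP (-6.66 ± 0.71) and pnp (-0.86 ± 0.22) fell and tig rose (1.11 ± 0.19) over all genes, 8 fell and 1 rose when adjusted over the list alone, and camera gave an unadjusted p of 0.0146 (0.34 with an estimated correlation). Cold handling and an effect of the deletion therefore cannot be told apart, and the second was not tested, because the handling of each group is not given in the sources used here.

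The fim decrease is not explained by loss of the genes from all cells, since fimA still reached at least 2030 CPM in each ΔsapD library. That value cannot exclude loss from a part of the cells. A candidate explanation is that the invertible fim promoter was off in more ΔsapD cells. The test written in advance took this to predict little change of fimB and fimE, which lie upstream of the invertible element. Their mean log2 fold change was -1.66, with fimB at -0.09 ± 0.60 and fimE at -3.24 ± 0.38, against a median of -3.75 over the 7 genes downstream. In this test fimB met the prediction and fimE did not. The fimE gene is transcribed towards the invertible element, so its level may itself depend on the orientation. Its fall therefore cannot be counted against phase switching. Loss from a part of the cells, phase switching, other regulation and a difference between founder cultures stay open.

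In ΔsapD pyrL fell and pyrB rose. Per 100 pyrB counts there were 0.106 and 0.151 pyrL counts in ΔsapD. The reporter libraries had 4.87 and 6.81 (high) and 11.3 and 10.9 (low), a gap to ΔsapD of at least 5.01 on the log2 scale. One candidate explanation is that the reporter construct carries the leader and adds pyrL reads to the high and low libraries. More pyrL would then be looked for in high cells, but pyrL hardly differed (high minus low log2 fold change 0.09 ± 0.40). The construct is not described in the sources used here, so this does not decide the question. Whether the ΔsapD strain carried the reporter is not given either. Reads from a construct and an effect of the deletion on the leader, attenuation included, therefore cannot be told apart, and the second was not tested.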
